A study of Mus musculus with 12 samples.

How the data were processed

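Whole-retina RNA of WT and 5xFAD mice at 1 and 6 months was measured as polyadenylated RNA in 12 libraries, 3 in each of 4 groups, from an unstranded preparation. The deposited tables hold expected counts per gene and per transcript, which the authors made before deposit and which are not normalised. The submitters' processing notes name Trim Galore 0.6.6, STAR 2.7.1a, RSEM 1.3.3, DESeq2 1.32.0 and the build GRCm38.p6, without their order and without the annotation used. The values are non-negative and partly fractional, and column totals are equal in both tables, as RSEM output gives. Totals ran from 10.9 to 19.6 M counts per library, and the most abundant gene held at most 2.72% of a library. Between replicates, the chi-square per degree of freedom over genes ran from 4.13 to 28.4, so no library is a copy of another. Counting error alone is smaller than the spread between replicates. Raw reads were not used here, and no human transgene sequence is in the tables.

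Expected counts were rounded and tested in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1 (and the package data.table, version 1.17.8). The edgeR quasi-likelihood fit (TMM scaling, filterByExpr by group, robust) held all 12 libraries with 8 residual degrees of freedom, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. Of 55487 genes and 142699 transcripts, 16233 and 45326 were tested. Genes and transcripts were matched by identifier to GENCODE M21 on GRCm38 (55227 genes and 141469 transcripts), which also gave coordinates, lengths and the 21843 transcripts of the retained-intron class. Comparisons were 5xFAD against WT at each age, 6 against 1 month in each genotype, the interaction of genotype and age, and 5xFAD against WT averaged over both ages. Gene lists of retinal cell types, cell processes, signs of RNA quality and other tissues (34 fixed, 32 with at least 5 tested genes) were tested with limma camera at a preset correlation of 0.01 on log2 CPM (prior count 2), and again with an estimated correlation and with fry. The retained-intron share of a gene was tested in edgeR on paired columns of retained-intron and other counts, each with a mean of at least 10 counts. The overall share was compared with an exact permutation test, which cannot go below p = 0.1 here. Comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined.

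Named genes followed a rule. App and Thy1 are given in every sample. Some results that the rule made eligible are not reported here. Per comparison the 8 largest changes up and down are eligible among called genes with a mean of at least 1 CPM and no overlap of the groups. Per list up to 4 members with the smallest p are eligible, and for lists of other tissues the 2 most abundant members. The genes Nnt, Wdfy1, Entpd4, Pde6b and Crb1, which differ between common mouse strains, are eligible too. For transcripts the 6 largest changes up and down are eligible, and for the retained-intron share the 6 smallest p. Where fewer than 5 passed, the 5 smallest p are named and said not to pass. Predicted genes are counted but not named, unless said to have been chosen after their values were seen. Alternatives were DESeq2 1.42.0 size factors, library size alone, the DESeq2 Wald test, other filters (1 count in all, or 1 CPM in 3 samples), a 2-fold minimum, the replicate number as a block, a fit of the 6 samples compared, and each replicate left out. For the share they were a minimum of 50 counts and limma on its logit with 0.5 added to each count. After the data were seen, further alternatives were added: removal of each library's trend on transcript length and GC content (splines with 4 degrees of freedom), the 3 libraries richest in ribosomal RNA left out, and pseudogenes, mitochondrial and ribosomal RNA genes left out. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

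The steps were tested on simulated data with the spread and depth of these libraries. Of genes changed 1.5-fold, 2-fold and 4-fold at 1 month, edgeR called 16 of 67, 32 of 67 and 52 of 66, with 4 false calls, and 1 false call at 6 months, where nothing was changed. In the interaction it called 4 of 67, 24 of 67 and 49 of 66, with 6 false calls. For transcripts at 1 month the figures were 0 of 67, 1 of 67 and 5 of 66, and at a mean of at least 10 CPM 0 of 67, 2 of 67 and 31 of 66. In the interaction they were 0 of 67, 0 of 67 and 1 of 66, and at 10 CPM 0 of 67, 0 of 67 and 9 of 66. For the retained-intron share at 1 month they were 0 of 67, 0 of 67 and 0 of 66, and with a minimum of 50 counts 0 of 67, 1 of 67 and 28 of 66. A list changed in the simulation was called. A length trend put into 3 simulated libraries gave 3340 calls before its removal and 0 after.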

Results

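Polyadenylated RNA from whole mouse retina was sequenced in WT animals (C57BL/6J) and in 5xFAD animals (strain label Tg6799), an Alzheimer disease model that carries a mutant human APP transgene driven by the Thy1 promoter. Retinas of each genotype were sampled at 1 and at 6 months of age, with 3 libraries in each of the 4 groups. The comparisons ask how gene, transcript and retained-intron levels differ between the genotypes at each age, and how they differ between the ages within each genotype. Expected counts per library came to 11.7, 11.3 and 11.4 M in WT at 1 month and 11.7, 10.9 and 11.2 M in 5xFAD at 1 month. At 6 months they came to 14.7, 19.6 and 16.7 M in WT and 12, 12.5 and 14.1 M in 5xFAD. Between 17073 and 21033 of 55487 annotated genes had a count in a library, and 16233 genes and 45326 transcripts had enough counts to test. The labels do not say that each library came from a separate animal, so the p-values measure the spread between samples. Values after ± are SD over the 3 libraries of a group for counts scaled to library size (CPM) and shares. For log2 fold changes and log2 odds ratios they are an approximate SE, the absolute log2 value over the square root of the edgeR F statistic. Where a pair of counts adjusted over the list alone stands in brackets, the first is of genes higher and the second of genes lower. Positions are on GRCm38.

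The libraries also differed in composition. Mitochondrially encoded genes took 4.96 ± 0.822% of the counts in WT at 1 month, 3.04 ± 0.107% in 5xFAD at 1 month, 6.04 ± 0.571% in WT at 6 months and 5.05 ± 0.0513% in 5xFAD at 6 months. The mean transcript length behind a count, in the same order of groups, was 4099 ± 113, 4592 ± 13.1, 4349 ± 195 and 4056 ± 43.9 nt. Annotated pseudogenes took 2.57 ± 0.372%, 1.60 ± 0.0294%, 1.25 ± 0.12% and 2.68 ± 0.0632%. Some of these are nuclear copies of mitochondrial genes, and WT at 6 months split counts differently between gene and copy. By library total, mt-Co3 read 6622 CPM there and 623 in the other 9 libraries, and its copy 269 and 6218. The mitochondrial and pseudogene shares of that group are therefore not comparable with those of the other groups. Ribosomal RNA took the largest share in 5xFAD at 6 months replicates 1 (1.11%) and 2 (0.446%) and in WT at 1 month replicate 2 (0.325%). On the genes that bear on this transgene, mouse App (chromosome 16, 84949685 to 85173766) read 276, 233 and 323 CPM in WT at 1 month and 317, 352 and 359 in 5xFAD at 1 month. At 6 months it read 318, 316 and 302 in WT and 288, 289.7 and 279 in 5xFAD. Thy1, which marks retinal ganglion cells, read 154, 179 and 168 CPM in WT and 165, 161 and 174 in 5xFAD at 1 month, then 144, 154 and 171 in WT and 172, 177 and 176 in 5xFAD at 6 months. These mouse-gene counts do not test for human transgene RNA, which was not analysed here.

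At 1 month, 5xFAD retinas had less RNA for ribosomal proteins and for the respiratory chain than WT retinas, and more of the genes of the synapse list that passed the threshold were higher than lower. Of 52 cytosolic ribosomal protein genes, 51 fell and 1 did not pass the edgeR test (52 fell adjusted over the list alone). The ribosomal protein list had a camera adjusted p of 1.77e-20, and adjusted p = 0.347 with an estimated correlation. Rpl11 fell from 161 ± 20.3 to 83.8 ± 2.53 CPM (log2 fold change -0.94 ± 0.11, adjusted p 4.91e-06), and Rps24, Rps21 and Rpl30 fell with it. Among 58 nuclear genes of oxidative phosphorylation, 46 fell and none rose (49 fell adjusted over the list alone). The oxidative phosphorylation list had a camera adjusted p of 5.25e-17, and adjusted p = 0.347 with an estimated correlation. The ATP synthase subunit gene Atp5g3 (-0.72 ± 0.10), Ndufa4 (-0.68 ± 0.09) and Cox7a2 (-0.84 ± 0.12) were among them. The genes encoded in mitochondrial DNA went the same way: 7 of 13 fell (10 adjusted over the list alone), with mt-Co1 going from 17084 ± 2464 to 9839.8 ± 352 CPM. The mitochondrially encoded gene list had a camera adjusted p of 3.24e-05, and adjusted p = 0.347 with an estimated correlation. In the same libraries, the share of counts from short transcripts was lower. With genes put in 3 equal groups by length, 78 of the shortest group rose and 959 fell, and 1455 of the longest group rose and 151 fell. Of 39 synapse genes, 13 rose, 1 fell and 25 did not pass (14 and 2 adjusted over the list alone). The synapse list had a camera adjusted p of 0.00236, and adjusted p = 0.347 with an estimated correlation. The active-zone scaffold Bsn rose from 126 ± 13 to 239 ± 33.0 CPM (log2 fold change 0.92 ± 0.11, adjusted p 8.71e-06), and the neurexin gene Nrxn3 rose by 0.87 ± 0.12 on the log2 scale.

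Genes of the retinal cell types moved in both directions at 1 month, and none of the lists of neuronal or glial markers passed the camera test in this comparison. Of 32 rod photoreceptor genes, 10 rose and 4 fell (11 and 4 adjusted over the list alone). The retinal guanylate cyclases Gucy2f (184 ± 23.1 to 435 ± 23.5 CPM; log2 fold change 1.24 ± 0.13, adjusted p 4.91e-06) and Gucy2e (0.65 ± 0.08) were higher. Of 16 cone genes, 4 rose and 4 fell (4 and 4 adjusted over the list alone): cone arrestin, Arr3, fell by 0.96 ± 0.11 while the exchanger gene Slc24a2 rose by 0.95 ± 0.14. Bipolar cell markers gave 6 higher and 2 lower of 19 (6 and 3 adjusted over the list alone), with nyctalopin, Nyx, at 1.56 ± 0.24. The counts were 3 higher and 1 lower of 18 for amacrine cells (3 and 1 adjusted over the list alone) and 1 and 0 of 7 for horizontal cells (1 and 0 adjusted over the list alone). They were 2 and 3 of 19 for ganglion cells (2 and 3 adjusted over the list alone) and 3 and 5 of 18 for Müller glia (3 and 7 adjusted over the list alone). Among these, the ganglion cell gene Sncg, gamma-synuclein, fell from 98.2 ± 19.0 to 56.0 ± 0.540 CPM, and the Müller glia channel genes Kcnj10 (0.85 ± 0.13) and Aqp4 (0.68 ± 0.11) rose. Genes of APP processing and Alzheimer risk gave 6 higher and 0 lower of 26 (7 and 1 adjusted over the list alone; camera adjusted p 0.126). The APP sorting receptor Sorl1 rose from 87.8 ± 10.0 to 161 ± 14.2 CPM (log2 fold change 0.87 ± 0.11, adjusted p 1.44e-05). Mouse App itself was at 0.31 ± 0.10, adjusted p 0.0293, with adjusted p 0.0564 without WT replicate 1, 0.204 without WT replicate 2, 0.105 without 5xFAD replicate 2 and 0.113 without 5xFAD replicate 3. Splicing factors split evenly, with 12 higher and 12 lower of 62 (13 and 14 adjusted over the list alone; camera adjusted p 0.569). The splicing regulators Celf2 (0.94 ± 0.10) and Sfpq (0.72 ± 0.10) were higher. Lists of microglia (16 homeostatic and 16 disease-associated genes) and of interferon and antigen presentation (23 genes) had no member past the edgeR threshold over all genes or adjusted over the list alone. Of 17 glial reactivity genes 1 rose, the ceruloplasmin gene Cp (0.58 ± 0.13).

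Markers of tissue next to the neural retina also differed at 1 month. Of 15 retinal pigment epithelium and choroid genes, 5 fell, 1 rose and 9 did not pass (1 higher and 7 lower adjusted over the list alone). The pigment epithelium list had a camera adjusted p of 0.00464, and adjusted p = 0.347 with an estimated correlation. Rpe65, the isomerohydrolase of the visual cycle, fell from 8.42 ± 3.71 to 1.25 ± 0.392 CPM (log2 fold change -2.74 ± 0.46, adjusted p 2.02e-04). Ttr, which encodes the retinol carrier transthyretin, fell from 43.0 ± 14.6 to 8.79 ± 3.01 CPM. The visual cycle list, which shares Rgr, Rdh5, Lrat, Rpe65, Stra6 and Ttr with it, had 7 lower and 3 higher of 15 (3 and 9 adjusted over the list alone). The visual cycle list had a camera adjusted p of 0.0489, and adjusted p = 0.347 with an estimated correlation. The photoreceptor retinoid-binding protein gene Rbp3 rose (0.65 ± 0.07). Of 18 endothelial genes, 3 rose and none fell (3 and 0 adjusted over the list alone), with the VEGF receptor gene Kdr at 0.72 ± 0.11, adjusted p 6.30e-05. The endothelial list had a camera adjusted p of 0.0280, and adjusted p = 0.347 with an estimated correlation. The collagen VI gene Col6a1 (chromosome 10, 76708792 to 76726168) had the smallest adjusted p of all genes, going from 199.7 ± 5.57 to 76.8 ± 5.64 CPM (log2 fold change -1.38 ± 0.09, adjusted p 5.51e-09). Of the wider list, 4 of 14 fibroblast and scleral genes fell and none rose (camera adjusted p 0.126). Among the largest folds of named genes were those of Cryaa, the lens alpha-crystallin gene (0.118 ± 0.138 to 18.9 ± 18.2 CPM, log2 fold change 7.23 ± 1.23, adjusted p 0.00173) and the potassium channel gene Kcnh5 (3.83 ± 1.40 to 25.9 ± 1.80 CPM), both higher. The GABA-B receptor auxiliary subunit gene Kctd16 (2.60 ± 0.41) and the kinase gene Hipk2 (2.36 ± 0.37) were higher too, and the lactate transporter gene Slc16a8 (-3.17 ± 0.74) was lower.

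In all, edgeR called 3178 of 16233 genes between the genotypes at 1 month, 1732 higher and 1446 lower in 5xFAD, of which 481 changed at least 2-fold. For each gene called and named here, the 3 libraries of a genotype did not overlap with those of the other except for App. The rule for naming asked for no overlap or took the smallest p, so this separation is no further support. The count was 1893 without WT at 1 month replicate 2, and 2097 without 5xFAD at 1 month replicate 2. With each library's trend on transcript length and GC content removed, 2015 genes were called, 826 higher and 1189 lower. The camera call was lost for the visual cycle without WT replicates 1 and 3 (adjusted p 0.0519 and 0.0959) or 5xFAD replicate 2 (0.105), and also with scaling by library size alone (0.0563) and with the length and GC trend removed (0.0671). That of endothelium was lost without WT replicates 2 and 3 (0.0729 and 0.0959) or 5xFAD replicate 2 (0.0615), and without the 3 libraries richest in ribosomal RNA (0.0819). That of synapse was lost with the length and GC trend removed (0.0671).

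**Figure D1:**
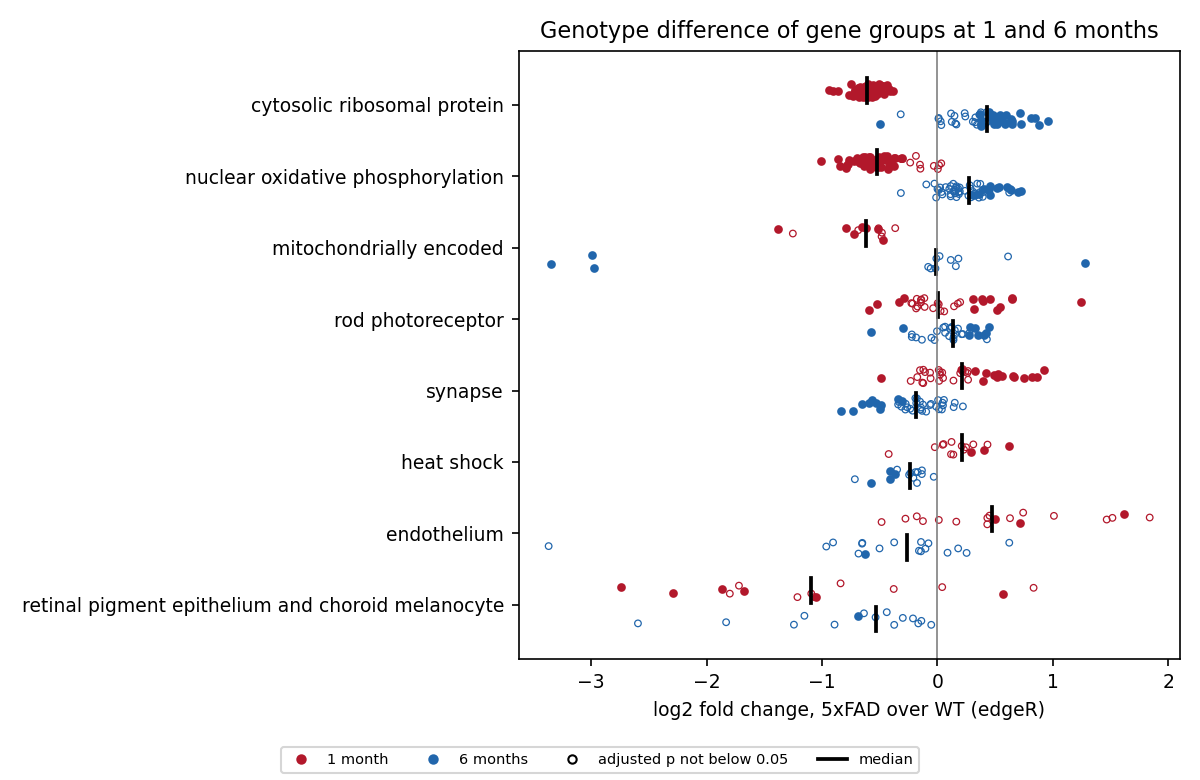
Log2 fold changes (5xFAD over WT) of the members of 8 gene lists at 1 month (red) and at 6 months (blue), with filled points for adjusted p below 0.05 and a bar at the median of each list. The ribosomal protein median was -0.61 at 1 month and 0.42 at 6 months, and the synapse median was 0.21 and -0.18.

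At 6 months many ribosomal protein genes and some nuclear oxidative phosphorylation genes were higher in 5xFAD than in WT retinas, and some synapse and heat-shock genes were lower. Of 52 ribosomal protein genes, 28 rose, 1 fell and 23 did not pass (38 and 2 adjusted over the list alone). The ribosomal protein list had a camera adjusted p of 2.29e-17, and adjusted p = 0.494 with an estimated correlation. Rps4x rose from 171 ± 23.8 to 298 ± 14.4 CPM (log2 fold change 0.81 ± 0.10, adjusted p 1.95e-05), and Rps19 by 0.88 ± 0.13. Of 58 nuclear oxidative phosphorylation genes, 13 rose and none fell (26 and 0 adjusted over the list alone), with Atp5g3 at 0.64 ± 0.10 and Ndufa4 at 0.60 ± 0.09. The oxidative phosphorylation list had a camera adjusted p of 1.97e-11, and adjusted p = 0.494 with an estimated correlation. In these libraries 253 genes of the group with the shortest transcripts rose and 43 fell, against 41 and 502 in the group with the longest. Of 39 synapse genes, 10 fell and none rose (0 and 12 adjusted over the list alone). The synapse list had a camera adjusted p of 1.33e-04, and adjusted p = 0.382 with an estimated correlation. The postsynaptic scaffold Shank1 fell from 131 ± 3.85 to 73.4 ± 11.4 CPM (log2 fold change -0.84 ± 0.12, adjusted p 1.89e-04), the release-site gene Rims1 by 0.74 ± 0.11 and Bsn by 0.65 ± 0.11. Of 15 heat-shock genes, 4 fell and none rose (0 and 5 adjusted over the list alone). The heat shock list had a camera adjusted p of 9.45e-04, and adjusted p = 0.494 with an estimated correlation. Hspa5 (-0.41 ± 0.10) is among the 4, with adjusted p 0.0617 without WT replicate 3, 0.0591 without 5xFAD replicate 1 and 0.0526 without 5xFAD replicate 2.

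Rod photoreceptor genes were higher as a set at 6 months, with 7 of 32 higher and 2 lower (11 and 4 adjusted over the list alone). The rod list had a camera adjusted p of 0.00895, and adjusted p = 0.494 with an estimated correlation. Of 16 cone genes 3 rose and none fell (4 and 1 adjusted over the list alone; camera adjusted p 0.156). Of 19 bipolar cell genes 4 fell and none rose (0 and 4 adjusted over the list alone), and of 18 amacrine cell genes 2 fell (0 and 4 adjusted over the list alone). Of 7 horizontal cell genes 2 fell (0 and 3 adjusted over the list alone) and of 18 Müller glia genes 2 fell (0 and 2 adjusted over the list alone). None of the amacrine, horizontal or Müller genes rose past the threshold. Elavl3, a neuronal RNA-binding protein gene, fell by 0.51 ± 0.10 and the circadian nuclear receptor gene Rorb rose by 0.49 ± 0.11. Kdr, higher in 5xFAD at 1 month, was lower at 6 months (-0.62 ± 0.11, adjusted p 9.99e-04). It was the single called gene of 18 in the endothelial list (0 and 1 adjusted over the list alone; camera adjusted p 0.156). Pigment epithelium and choroid genes were lower as a set, with 1 of 15 past the gene threshold (median log2 fold change -0.54; 0 and 1 adjusted over the list alone). The pigment epithelium list had a camera adjusted p of 0.0243, and adjusted p = 0.587 with an estimated correlation. Genes of APP processing and Alzheimer risk gave 1 lower of 26 and none higher (0 and 1 adjusted over the list alone; camera adjusted p 0.270). Splicing factors gave 2 higher and 7 lower of 62 (4 and 7 adjusted over the list alone). The lists of microglia and of interferon and antigen presentation had none past the edgeR threshold over all genes or adjusted over the list alone.

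Among the largest folds at 6 months were those of genes that share sequence with near-identical copies. The pseudogene Rpl28-ps1 read 0.727 ± 0.0593 CPM in WT and 35.5 ± 16.3 CPM in 5xFAD (log2 fold change 5.6 ± 0.38, adjusted p 1.26e-08). Tpt1-ps3 and Rpl36a-ps2 were higher with it, and Srp54b, one of several near-identical Srp54 genes, was higher by 2.84 ± 0.23. The mitochondrial genes mt-Co3 (6588 ± 727 CPM in WT and 829 ± 255 in 5xFAD) and mt-Atp6 (-2.98 ± 0.37), which have nuclear copies, were lower. So was the mitochondrial ribosomal protein gene Mrpl23 (-2.00 ± 0.38), which has a pseudogene, and the assignment of these reads is uncertain. As a list, 1 of 13 mitochondrially encoded genes rose, 3 fell and 9 did not pass (1 and 3 adjusted over the list alone; camera adjusted p 0.385). In WT at 6 months mt-Co3 was high where its copy Gm28437, which was chosen after its values were seen, was low, as the plot of the pair shows. The edgeR fit called 1035 of 16233 genes, 403 higher and 632 lower in 5xFAD, with 167 changed at least 2-fold and 59 pseudogenes among the 1035. The genotypes did not overlap for any gene named with its values in this comparison, which the choice of these genes largely brings about. The count was 360 and 276 without WT at 6 months replicates 1 and 2 respectively, and 553, 583 and 1687 without 5xFAD at 6 months replicates 1, 2 and 3 respectively. It was 321 without the 3 libraries richest in ribosomal RNA, in which the calls of heat shock (adjusted p 0.247) and rod genes (0.0570) were lost. The rod call was lost without WT replicate 1 (adjusted p 0.0614), 5xFAD replicate 1 (0.0665) or 3 (0.0590). That of pigment epithelium was lost without WT replicates 1 and 3 (0.179 and 0.0917) or 5xFAD replicates 1 and 3 (0.258 and 0.181). With the rotation test fry the calls of ribosomal protein (adjusted p 0.0555), oxidative phosphorylation (0.0564), rod (0.0538) and pigment epithelium genes (0.132) were lost.

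**Figure D2:**
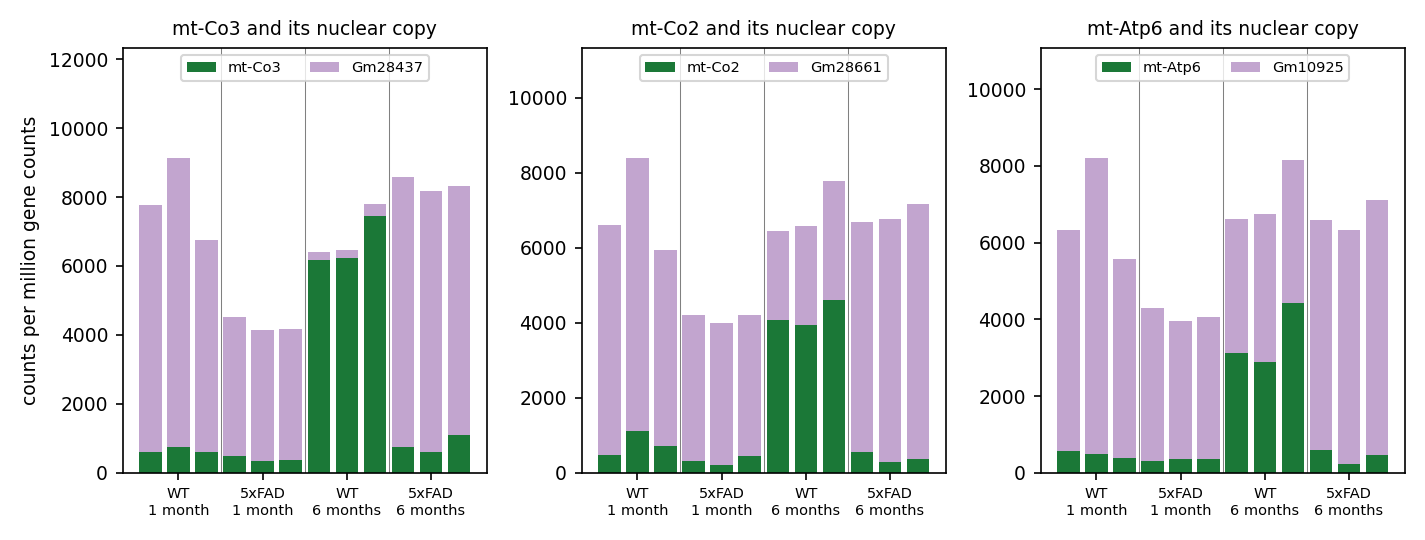
CPM by library total of mt-Co3, mt-Co2 and mt-Atp6 (green) and of the nuclear copy of each (purple) stacked in the 12 libraries. In WT at 6 months the mitochondrial gene held most of the mt-Co3 bar and the copy little of it.

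Whether the genotype difference itself changed with age was tested as the interaction of genotype and age, whose log2 value is the difference at 6 months minus the difference at 1 month. Ribosomal protein and respiratory genes shifted towards 5xFAD. In this test 48 of 52 ribosomal protein genes were higher and none lower (49 and 0 adjusted over the list alone), as were 47 of 58 nuclear oxidative phosphorylation genes (52 and 0 adjusted over the list alone). The ribosomal protein list had a camera adjusted p of 3.61e-22, and adjusted p = 0.405 with an estimated correlation. The oxidative phosphorylation list had a camera adjusted p of 9.24e-18, and adjusted p = 0.405 with an estimated correlation. Rps4x shifted by 1.43 ± 0.14, adjusted p 1.91e-07, and Atp5g3 by 1.36 ± 0.14, adjusted p 5.33e-07. Synaptic genes shifted the other way, with 19 of 39 lower and 1 higher (1 and 21 adjusted over the list alone). The synapse list had a camera adjusted p of 1.36e-04, and adjusted p = 0.383 with an estimated correlation. Bsn went from 126 ± 13 CPM in WT and 239 ± 33.0 in 5xFAD at 1 month to 177 ± 23.6 in WT and 112 ± 3.04 in 5xFAD at 6 months (interaction -1.58 ± 0.16, adjusted p 4.21e-07). Of 15 heat-shock genes 7 were lower and none higher (0 and 8 adjusted over the list alone). The heat shock list had a camera adjusted p of 0.00463, and adjusted p = 0.405 with an estimated correlation. Of 18 endothelial genes 3 were lower and none higher (0 and 3 adjusted over the list alone), among them Kdr (-1.34 ± 0.15). The endothelial list had a camera adjusted p of 0.0323, and adjusted p = 0.496 with an estimated correlation. Splicing factors split evenly, 13 of 62 lower and 13 higher (13 and 14 adjusted over the list alone; camera adjusted p 0.880), with Celf2 (-1.32 ± 0.14), Rbfox2 (-1.25 ± 0.15) and Sfpq (-1.23 ± 0.14) lower. Of 26 genes of APP processing and Alzheimer risk, 9 were lower and none higher (0 and 9 adjusted over the list alone; camera adjusted p 0.151), with Sorl1 at -1.22 ± 0.16, adjusted p 6.71e-06. Kcnh5 (-4.34 ± 0.41), Hipk2 (-3.82 ± 0.52) and the glycine receptor subunit gene Glra1 (-4.31 ± 0.90) were among the largest shifts down. The kinesin gene Kif4 (3.26 ± 0.42) was among the largest up. The edgeR fit called 4054 of 16233 genes, 1892 higher and 2162 lower, and 1532 of them by at least 2-fold. Of 673 genes called at both ages, 668 differed in opposite directions (469 higher and then lower in 5xFAD, 199 lower and then higher). Of the rest, 2 were higher at both ages and 3 lower at both, against 103 opposite, 43.0 higher and 56.3 lower from independent calls. Across genes, which are not independent replicates, the log2 fold changes at the 2 ages had a Spearman correlation of -0.41. Transcript length went with the direction here too: in the group with the shortest transcripts 1157 genes were higher and 112 lower, in the longest 228 and 1723. Without the 3 libraries richest in ribosomal RNA 2354 genes were called, and the heat-shock call was lost (adjusted p 0.0502). Single libraries ended the endothelial call. At 1 month these were WT replicates 2 and 3 (adjusted p 0.0548 and 0.0923) and 5xFAD replicate 2 (0.0557). At 6 months they were WT replicate 3 (0.0799) and 5xFAD replicates 1 and 3 (0.0536 and 0.114).

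**Figure D3:**
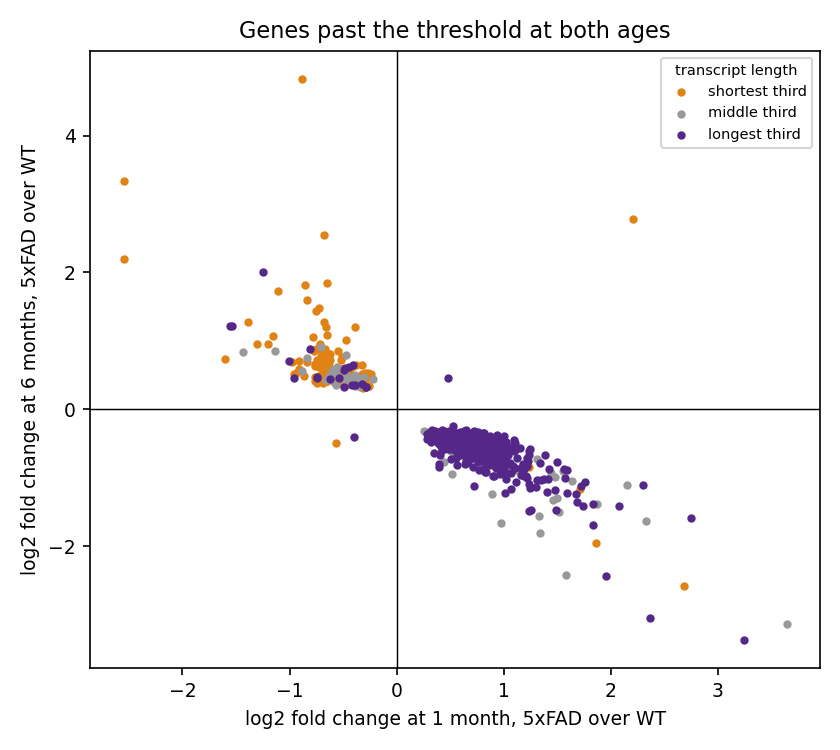
Log2 fold change (5xFAD over WT) at 1 and at 6 months for 669 of the 673 genes called at both ages, coloured by group of transcript length (shortest, middle, longest), with 4 genes left out for lack of a count in a group or of a length.

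In the mean of the genotype differences at 1 and 6 months the called genes were few, and they included collagen VI chains and the photoreceptor gene Rbp3 beside pseudogenes. Col6a1 fell by 0.78 ± 0.07, adjusted p 3.69e-07. It stood at 139 ± 9.78 CPM in WT and 123 ± 3.68 CPM in 5xFAD at 6 months. Such a mean can pass on 1 age alone, and at 6 months by itself Col6a1 did not pass (-0.19 ± 0.09, adjusted p 0.252). Col6a6, a further collagen VI chain gene, fell by 1.33 ± 0.24. Rbp3 was higher by 0.32 ± 0.05, adjusted p 0.00222. Rpe65 (-1.69 ± 0.31) and Sncg (-0.54 ± 0.09) were lower. The Y-linked RNA helicase gene Ddx3y was higher at both ages: 54.7 ± 5.24 CPM in WT and 76.3 ± 2.98 in 5xFAD at 1 month and 55.7 ± 7.72 and 76.7 ± 2.75 at 6 months (log2 fold change 0.47 ± 0.08, adjusted p 0.00546). The X-linked ubiquitin ligase gene Mid1 was higher on average (0.59 ± 0.11). Strain goes with genotype by the labels, and sex was not in the models. These and the other genotype differences therefore cannot be told apart from strain, and a part of sex in them was not tested. The ribosomal protein gene Rps23, which has a pseudogene, was lower on average (-0.54 ± 0.08). By library total Rps23 read 140 CPM in WT at 6 months and 83.0 in the other libraries, and that pseudogene 24.2 and 74.0. Their sum hardly differed (log2 difference 0.068), so the lower Rps23 is not told apart from the split of reads between them. The edgeR fit called 104 of 16233 genes, 55 higher and 49 lower, of which 19 are pseudogenes and 6 mitochondrially encoded. The count was 54 without WT at 1 month replicate 2, 43, 43 and 60 without 5xFAD at 1 month replicates 1, 2 and 3 respectively, and 67 and 62 without WT at 6 months replicates 1 and 2 respectively. It was 315 with the DESeq2 Wald test and 195 with the length and GC trend removed. Scaling by library size alone gave 30 higher and 62 lower.

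In WT retinas some heat-shock and histone genes were higher at 6 months than at 1 month, and globin genes and some respiratory genes were lower. Of 15 heat-shock genes 7 rose and none fell (11 and 0 adjusted over the list alone). The heat shock list had a camera adjusted p of 4.22e-06, and adjusted p = 0.204 with an estimated correlation. Hspa8 went from 869.5 ± 21.7 to 1356 ± 147 CPM (log2 fold change 0.64 ± 0.10, adjusted p 2.51e-04), and Hsph1 was at 0.89 ± 0.16. Of 12 replication-dependent histone genes, whose RNA mostly lacks a poly(A) tail, 4 rose and 1 fell (5 and 1 adjusted over the list alone), with Hist1h2bc at 0.54 ± 0.11 and Hist1h1e at 1.53 ± 0.38, whose reads are uncertain since 25.7% of its exon bases lie in Hist1h2be. The histone list had a camera adjusted p of 0.00553, and adjusted p = 0.224 with an estimated correlation. Globin genes accounted for the 4 of 8 blood genes that fell (0 and 4 adjusted over the list alone). The blood list had a camera adjusted p of 2.44e-04, and adjusted p = 0.204 with an estimated correlation. Hba-a1 went from 20.7 ± 10.1 to 3.42 ± 0.749 CPM and Hbb-bs from 52.1 ± 23.4 to 6.62 ± 2.06 CPM, each beside a near-identical copy. Of 58 oxidative phosphorylation genes 15 fell and none rose (0 and 26 adjusted over the list alone), and of 52 ribosomal protein genes 11 fell and 2 rose (2 and 18 adjusted over the list alone). The oxidative phosphorylation list had a camera adjusted p of 2.98e-08, and adjusted p = 0.545 with an estimated correlation. The ribosomal protein list had a camera adjusted p of 2.35e-05, and adjusted p = 0.818 with an estimated correlation. Ndufa4 fell by 0.77 ± 0.09 and Rps4x by 0.65 ± 0.10. Of 39 synapse genes, 10 rose and 1 fell (11 and 2 adjusted over the list alone; camera adjusted p 0.0508), with Shank1 at 0.70 ± 0.12. Among cell type markers, the photoreceptor gene Gucy2e rose by 0.41 ± 0.08. The Müller glia genes Kcnj10 (0.93 ± 0.13) and Aqp4 (0.65 ± 0.11) rose and Crym fell (-1.03 ± 0.14), within 5 higher and 1 lower of 18 (6 and 4 adjusted over the list alone). Rorb fell (354 ± 30.6 to 206 ± 30.1 CPM) and the clock-controlled protease gene Usp2 rose (0.58 ± 0.10). Of 20 circadian genes, 3 were higher and 6 lower (6 and 7 adjusted over the list alone). The edgeR fit called 1705 genes, 976 higher and 729 lower at 6 months. The ages did not overlap for the named genes, which their choice largely brings about. The count was 845 without WT at 1 month replicate 2, and 846 and 780 without WT at 6 months replicates 1 and 2 respectively. The ribosomal call was lost with the length and GC trend removed (adjusted p 0.478). With fry the calls of ribosomal protein (0.265) and oxidative phosphorylation genes (0.0606) were lost.

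In 5xFAD retinas the change from 1 to 6 months took in more genes than in WT, with ribosomal, respiratory, synaptic and vascular genes among them. Of 52 ribosomal protein genes 51 rose and none fell (51 and 0 adjusted over the list alone). The ribosomal protein list had a camera adjusted p of 4.53e-27, and adjusted p = 0.374 with an estimated correlation. Rpl11 went from 83.8 ± 2.53 to 183 ± 1.22 CPM (log2 fold change 1.12 ± 0.11, adjusted p 5.85e-07). Of 58 nuclear oxidative phosphorylation genes 46 rose and none fell (49 and 0 adjusted over the list alone), as did 8 of 13 mitochondrially encoded genes (8 and 0 adjusted over the list alone). The oxidative phosphorylation list had a camera adjusted p of 7.93e-17, and adjusted p = 0.374 with an estimated correlation. The mitochondrially encoded gene list had a camera adjusted p of 2.52e-05, and adjusted p = 0.395 with an estimated correlation. Atp5k was at 1.20 ± 0.14 and mt-Cytb at 0.85 ± 0.10. Transcript length went with these changes: 1159 genes rose and 104 fell in the group with the shortest transcripts, 156 and 1633 in the longest. Of 39 synapse genes 21 fell and 2 rose (2 and 21 adjusted over the list alone), with Bsn at -1.09 ± 0.11, adjusted p 1.14e-06 and the complexin gene Cplx2 at -0.63 ± 0.10. The synapse list had a camera adjusted p of 4.21e-05, and adjusted p = 0.311 with an estimated correlation. Of 18 endothelial genes 8 fell and none rose (0 and 10 adjusted over the list alone). The endothelial list had a camera adjusted p of 8.49e-05, and adjusted p = 0.374 with an estimated correlation. The endothelial genes that fell include Kdr (179 ± 6.59 to 77.2 ± 5.69 CPM), the tight-junction gene Cldn5 (-2.30 ± 0.46) and Eng (-3.17 ± 0.67). Of 10 pericyte and smooth muscle genes 4 fell and 1 rose (camera adjusted p 0.0919), with Abcc9 at -1.97 ± 0.50. Globins and the haem synthesis gene Alas2 make up the 5 of 8 blood genes that fell in 5xFAD, with none rising (1 and 5 adjusted over the list alone). The blood list had a camera adjusted p of 0.0360, and adjusted p = 0.374 with an estimated correlation. Hba-a2 went from 30.8 ± 9.95 to 7.32 ± 2.26 CPM. The blood call was lost without 5xFAD at 1 month replicate 1 (adjusted p 0.0825) or 5xFAD at 6 months replicate 3 (0.0802). The rod genes Gngt1 (1.05 ± 0.11) and Guca1a (1.11 ± 0.12) rose and Gucy2f fell (-1.21 ± 0.13), within 9 higher and 9 lower of 32 (12 and 10 adjusted over the list alone). Arr3 rose from 226 ± 32.1 to 494 ± 40.7 CPM, within 5 higher and 1 lower of 16 cone genes (5 and 2 adjusted over the list alone). Among marker genes of microglia, 4 of 16 disease-associated and 2 of 16 homeostatic microglia genes rose with none falling (4 and 0 adjusted over the list alone and 2 and 0 adjusted over the list alone; camera adjusted p 0.165 and 0.0859), and neither list passed. Among the genes that rose was Gpnmb (2.62 ± 2.27 to 9.20 ± 2.06 CPM). The basement membrane collagen gene Col4a3 rose from 6.53 ± 2.75 to 62.9 ± 10.1 CPM (log2 fold change 3.27 ± 0.48, adjusted p 0.00111). The edgeR fit called 3772 genes, 1760 higher and 2012 lower at 6 months, and 1947 without the 3 libraries richest in ribosomal RNA. The ages did not overlap for the genes named with their values, which their choice largely brings about. Of 865 genes called with age in both genotypes, 758 changed in opposite directions, against 200 from independent calls.

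Some single transcripts, Arhgap35-202 and Arid1a-201 among them, were counted in 1 genotype only at an age. At 1 month, with no count in any WT library and against a floor of 3 counts per library, Arhgap35-202, from a GTPase-activating protein gene, was at least 314-fold higher in 5xFAD (82.2 ± 9.25 CPM). Arid1a-201, from a chromatin remodeller gene, was at least 300-fold higher. Trim2-204, from a ubiquitin ligase gene, had no count in 5xFAD and was at least 329-fold lower. The genes as a whole moved far less at 1 month, with log2 fold changes of 0.67 for Arhgap35 and 0.58 for Arid1a. The Trim2 gene was higher in 5xFAD (0.69, edgeR adjusted p 1.84e-05), against the direction of Trim2-204. At 6 months Arhgap35-202 and Arid1a-201 had no count in 5xFAD and were at least 236-fold and 186-fold lower than in WT. Srp54c-202 was at least 278-fold lower and Rtn1-205, from a reticulon gene, at least 187-fold higher. At 6 months the genes were at -0.33 (Arhgap35), -0.52 (Arid1a), -0.21 (Srp54c) and 0.0058 (Rtn1) on the log2 scale. Which transcript of a gene a read counts for is an estimate, so these transcript folds are bounds only if that estimate holds. The edgeR fit called 1144 of 45326 transcripts at 1 month (726 higher, 418 lower), 221 at 6 months (75 higher, 146 lower) and 2743 in the interaction (942 higher, 1801 lower). Between the ages it called 415 in WT (250 higher, 165 lower) and 1416 in 5xFAD (528 higher, 888 lower). The counts moved with single libraries. At 1 month they were 688 and 250 without WT at 1 month replicates 1 and 2 respectively, and 379, 316 and 443 without 5xFAD at 1 month replicates 1, 2 and 3 respectively. At 6 months they were 57, 36 and 433 without WT at 6 months replicates 1, 2 and 3 respectively, and 129, 129 and 486 without 5xFAD at 6 months replicates 1, 2 and 3 respectively. In WT with age they were 102 without WT at 1 month replicate 2, and 85 and 71 without WT at 6 months replicates 1 and 2 respectively. In 5xFAD with age they were 600, 432 and 533 without 5xFAD at 1 month replicates 1, 2 and 3 respectively, and 691 and 573 without 5xFAD at 6 months replicates 1 and 2 respectively. In the interaction they were 1525 without WT at 1 month replicate 2, 1654, 1556 and 1686 without 5xFAD at 1 month replicates 1, 2 and 3 respectively, and 1273 and 1102 without WT at 6 months replicates 1 and 2 respectively. With DESeq2 size factors the 6-month count was 101 higher and 112 lower. In the replicate block the calls of Srp54c-202, Arhgap35-202 and Arid1a-201 at 6 months were lost (adjusted p 0.0558, 0.0558 and 0.0558), as was that of Rtn1-205 (0.0661).

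Retained introns were measured as the transcripts that the annotation classes as retained intron. Their overall share of counts did not separate the genotypes. At 1 month it was 6.46% ± 0.0826 in 5xFAD and 6.42% ± 0.207 in WT (difference 0.0364, two-sided exact permutation p 0.8). At 6 months it was 6.09% ± 0.224 in 5xFAD and 6.39% ± 0.487 in WT (difference -0.302, exact permutation p 0.5). With 3 libraries against 3 the smallest p this test allows is 0.1. The 1-month difference was -0.0160 without WT replicate 2, -0.0304 without WT replicate 3 and -0.00623 without 5xFAD replicate 1. With age the share went by -0.0281 in WT (exact permutation p 1) and by -0.367 in 5xFAD (exact permutation p 0.1).

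Single retained-intron transcripts did differ, Sptbn1-207 and Sag-207 among them. The retained-intron transcript Sptbn1-207 of beta-spectrin (chromosome 11, 30099396 to 30103249) fell at 1 month from 80.2 ± 25.2 CPM in WT to 5.79 ± 1.09 CPM in 5xFAD (log2 fold change -3.79 ± 0.51, adjusted p 0.00806). The Sptbn1 gene itself rose in that comparison (log2 fold change 0.66, edgeR adjusted p 2.48e-05). Clip1-206, from a microtubule plus-end protein gene, had no count in 5xFAD at 1 month and was at least 58.3-fold lower. Rab23-208, from a small GTPase gene with a role at cilia, had none in WT and was at least 16.7-fold higher. At 6 months Immt-214, from a mitochondrial inner-membrane organiser gene, went from 2.00 ± 0.133 to 20.0 ± 5.79 CPM (log2 fold change 3.31 ± 0.48, adjusted p 0.0217). Slc12a5-205, from the neuronal chloride transporter gene, went from 14.7 ± 2.17 to 103 ± 40.7 CPM (2.82 ± 0.42, adjusted p 0.0250). Sag-207, from the rod arrestin gene, fell from 227 ± 25.1 to 75.0 ± 12.7 CPM (-1.60 ± 0.26, adjusted p 0.0311). The call of Immt-214 was lost without WT replicates 1 and 2 (adjusted p 0.115 and 0.121) and 5xFAD replicate 2 (0.0524). Without WT replicates 1 and 2 and 5xFAD replicates 1 and 2 those of Slc12a5-205 (0.117, 0.149, 0.0543 and 0.0555) and Sag-207 (0.117, 0.146, 0.103 and 0.0986) were lost. Of 9832 retained-intron transcripts tested, edgeR called 146 at 1 month (76 higher, 70 lower, and 86 adjusted over the list alone) from 132 genes. For 61 of these 146 transcripts the gene itself was called too. At 6 months edgeR called 20 (10 higher, 10 lower). Adjusted over the list alone none were called at 6 months by edgeR, with 886 at an unadjusted p below 0.05 and 582 by the DESeq2 Wald test over all transcripts. At 1 month 1.48% of retained-intron transcripts and 2.81% of other transcripts were called, and at 6 months 0.203% and 0.566%. The count at 1 month was 73 and 30 without WT at 1 month replicates 1 and 2 respectively, and 46, 40 and 57 without 5xFAD at 1 month replicates 1, 2 and 3 respectively. At 6 months it was 2, 0 and 53 without WT at 6 months replicates 1, 2 and 3 respectively, and 4, 1 and 54 without 5xFAD at 6 months replicates 1, 2 and 3 respectively. With DESeq2 size factors it was 11 higher and 7 lower at 6 months.

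The share of a gene's counts on retained-intron transcripts takes out the level of the gene. It rests on how RSEM split reads between overlapping transcripts, so a changed share is not shown to be changed intron retention. The rod arrestin gene Sag was among the genes in which the share differed at 1 month. Over all 4769 genes tested the median log2 odds ratio was 0.364 at 1 month and -0.291 at 6 months. Removal of the length and GC trend was not run for the share. For Sag (chromosome 1, 87803680 to 87845158) the share rose from 5.91% ± 0.903 in WT to 17.0% ± 0.0159 in 5xFAD (log2 odds ratio 1.71 ± 0.22, adjusted p 0.0110). C2cd2l rose from 1.82% ± 0.523 to 6.02% ± 0.17, and Pitpnm3, from a phosphatidylinositol transfer protein gene, from 0.978% ± 0.163 to 4.68% ± 0.177. The share of Sptbn1 (chromosome 11, 30099395 to 30268175) fell from 22.3% ± 7.50 to 3.38% ± 0.414 (-2.99 ± 0.34, adjusted p 0.00833), while the gene itself rose. That of Ginm1 fell from 29.1% ± 7.53 to 0.133% ± 0.230. At 6 months the share of Fry was higher in 5xFAD, 32.9% ± 7.25 against 4.38% ± 1.03 (3.42 ± 0.40, adjusted p 0.0118). The Fry gene itself was lower there (log2 fold change -0.71, edgeR adjusted p 0.00318). The shift of the genotype difference between the ages passed the interaction test for Sag (-2.87 ± 0.31, adjusted p 0.00142), Sptbn1 (5.21 ± 0.47, adjusted p 5.21e-04) and C2cd2l (-3.83 ± 0.34, adjusted p 5.21e-04). So did that for Fry (6.05 ± 0.57, adjusted p 5.27e-04) and Slc12a5 (5.01 ± 0.52, adjusted p 0.00142). In 5xFAD from 1 to 6 months the shares of Sag (-1.91 ± 0.22, adjusted p 0.00769) and of the disc protein gene Prph2 (-1.93 ± 0.27, adjusted p 0.0143) fell. In WT that of C2cd2l rose (2.40 ± 0.24, adjusted p 0.00461). The call of Prph2 was lost without 5xFAD at 1 month replicate 1 (adjusted p 0.0568). Of 4769 genes tested, 138 were called at 1 month (72 with a higher and 66 with a lower share, 54 of them called at the gene level too). Called were 9 at 6 months (4 higher, 5 lower) and 367 in the interaction (144 higher, 223 lower). With age 21 were called in WT (11 higher, 10 lower) and 138 in 5xFAD (75 higher, 63 lower). With a minimum of 50 counts 300 were called at 1 month and 89.0 at 6 months, with the replicate block in limma on the logit share 4.00 and 0, and without the 3 libraries richest in ribosomal RNA 26.0 and 0. Averaged over both ages edgeR called none, with 234 at an unadjusted p below 0.05. Of the 5 smallest p, which did not pass, Ppia had adjusted p 0.0965 and Ginm1 0.245. The count at 1 month was 3 without WT at 1 month replicate 2, and 20, 25 and 38 without 5xFAD at 1 month replicates 1, 2 and 3 respectively. At 6 months it was 0, 1 and 45 without WT at 6 months replicates 1, 2 and 3 respectively, and 4, 0 and 58 without 5xFAD at 6 months replicates 1, 2 and 3 respectively. With WT at 1 month replicate 2 out, the calls of Sag, Ginm1 and Pitpnm3 were lost (adjusted p 0.0553, 0.0553 and 0.0553). At 6 months the call of Fry was lost without WT replicates 1 and 2 and 5xFAD replicate 2 (adjusted p 0.0624, 0.0642 and 0.0721).

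**Figure D4:**
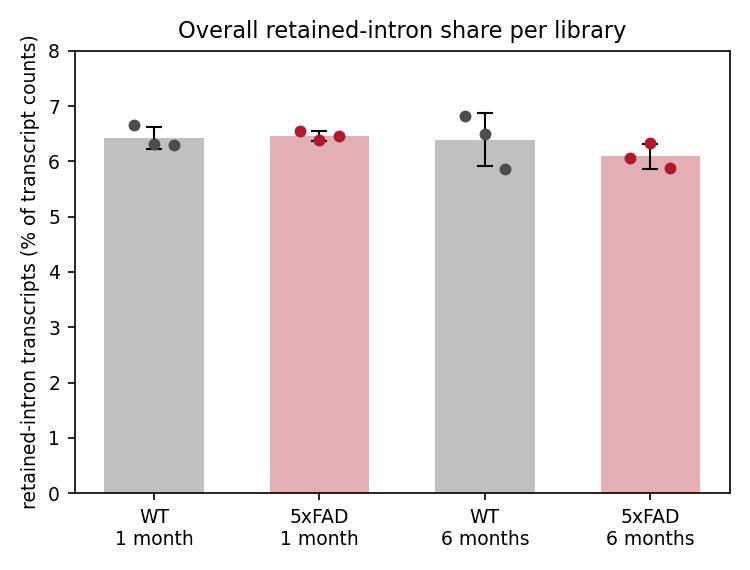
Retained-intron transcripts as a percentage of transcript counts in each library, with bars at group means and SD. The means were 6.42% and 6.46% at 1 month and 6.39% and 6.09% at 6 months for WT and 5xFAD.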

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

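The tests of exchanged labels, of copies of similar abundance and of pigment epithelium were chosen after the results were seen, as were the removal of the length and GC trend and of 3 libraries as alternatives. The genotype difference at 6 months differed from that at 1 month, by the interaction test, for 4054 genes such as Bsn and Rps4x, 2743 transcripts, the retained-intron share of 367 genes such as Sag and Sptbn1, and 5 lists, ribosomal protein and synapse genes among them. With an estimated correlation camera called 0 lists in the interaction (lowest adjusted p 0.383), against 7 at an unadjusted p below 0.05 with the preset one and 9 with fry. Groups of 3 were not searched for outlying libraries. On the first principal component (23.2% of the variance) WT at 1 month lay at -11.3, -40.3 and -14.8, and 5xFAD at 6 months at -61.1, -47.8 and -12.6. There 5xFAD at 1 month lay at 42.0, 49.2 and 39.8, and WT at 6 months at 25.8, 25.2 and 5.87. On the second (14.3%) 5xFAD at 6 months replicate 1 lay at -71.8, and replicates 2 and 3 at 12.6 and 4.05. The mean transcript length behind a count was 4124 nt in WT at 6 months replicate 3 against 4459 and 4465 nt, and its chi-square per degree of freedom to these was 15.9 and 16.3 against 4.13 between them. That of 5xFAD at 6 months replicate 3 to replicates 1 and 2 was 28.4 and 20.8, against 15.3 between them. Without 5xFAD replicate 1 553 genes were called at 6 months, and without WT replicate 3 1382, against 1035 with all. Without 5xFAD replicate 3 the count was 1687.

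Lists of ribosomal protein, nuclear oxidative phosphorylation and synapse genes differed between the genotypes in opposite directions at the 2 ages by camera with a preset correlation. With an estimated one they did not pass at 1 month (adjusted p 0.347, 0.347 and 0.347) or 6 months (0.494, 0.494 and 0.382). With fry the first 2 did not pass at 6 months (0.0555 and 0.0564), and with the length and GC trend removed synapse did not at 1 month (0.0671). Each library's trend on transcript length and GC content was removed. Of the genes called in the interaction 55.7% (2259 of 4054) were then called the same way. The 95% interval over genes was 54.2 to 57.3, but genes of the same libraries are not independent. That interval leaves out the spread between libraries. Calls thus remained without this smooth trend, but how much of the turn-over the trend made is not decided. Without the 3 libraries richest in ribosomal RNA 51.6% were called the same way. The 20 other sets of 3 libraries kept 28.6 to 83.2% (median 53.1%, SD 17.4), so a share of these libraries in the turn-over stays open. Genotype labels exchanged at 1 age could give it too: 5 genes were called the same way at both ages against 99.3 expected. A genotype effect that turns over with age would give such values as well, so this is not decided. A change of the genotype effect with age, which the design names, stays open too: the interaction test shows that the measured difference changed, but not why.

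The 3 WT libraries at 6 months stood apart from the other 9 in pseudogenes: 625 genes were called, 57 of them pseudogenes (44 lower, 13 higher), or 11.7% of pseudogenes against 3.61% of other genes. Reads assigned differently between near-identical copies are a candidate explanation: in 13 of 51 pairs the copy held at least 20% of the summed count, and there the sum differed by 0.144 of the copy's own difference in the median, as for mt-Co3 (623 to 6622 CPM) and its copy Gm28437 (6218 to 269 CPM), here scaled by library total alone. Over all pairs the value was 0.0525, which decides nothing since copies held a median of 7.14% of the sum. Pseudogenes and mitochondrially encoded genes made up 2.61% of the genes called in the interaction, but could not exceed 12.4% with 503 such genes tested, so a part of copies in the turn-over of the genotype difference is not decided. These libraries were also deeper, at a mean of 17 M counts against 11.5, 11.3 and 12.9 M in WT at 1 month, 5xFAD at 1 month and 5xFAD at 6 months. Genes detected averaged 20518 against 18350, 18843 and 17974. The labels used here name no batch, so a technical difference of this group cannot be told apart from its genotype and age. It would enter the comparisons at 6 months, with age in WT and in the interaction. The averages over both ages and over both genotypes would hold it too. Of the genes called between the genotypes averaged over both ages, 24.0% were pseudogenes or mitochondrially encoded, against 1.86% at 1 month and 6.18% at 6 months. No biological explanation was tested.

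Pigment epithelium genes were lower in 5xFAD at both ages as a list, with Rpe65 and Ttr among those called at 1 month and 1 of 15 genes called at 6 months. With an estimated correlation the list did not pass at 1 month (adjusted p 0.347) or 6 months (0.587). At 6 months it did not pass with fry either (0.132), nor without WT replicates 1 and 3 (0.179 and 0.0917) or 5xFAD replicates 1 and 3 (0.258 and 0.181). An unequal amount of pigment epithelium left on the retina is a candidate explanation that stays open. Between replicates of a group the 15 members moved together (mean pairwise r 0.245), against a median of -0.00354 and a 95th percentile of 0.0709 in 1000 random lists matched on expression (percentile 100). Of the 31 other lists, 17 lay above that 95th percentile too, so this does not point to unequal tissue in particular. Ttr read 43.0 ± 14.6 CPM in WT and 8.79 ± 3.01 CPM in 5xFAD at 1 month, and Rgr 38.3 ± 16.2 and 10.5 ± 3.98 CPM. The visual cycle list holds 6 of the members, and no sort that would remove the epithelium is in the labels. A genotype effect on the epithelium itself stays open too, and untested.

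Other splits of the samples were fitted the same way. For 3 libraries against 3 there are 10 splits, too few for a share below 0.05, so the real count and the highest of the others are given. For genes these were 3178 and 0 at 1 month, 1035 and 0 at 6 months, 1705 and 0 with age in WT and 3772 and 3 with age in 5xFAD. For transcripts they were 1144 and 2, 221 and 2, 415 and 2 and 1416 and 8 in the same order. For lists they were 7 and 7, 6 and 5, 5 and 9 and 6 and 7. At 1 and 6 months they were 146 and 0 and 20 and 0 for retained-intron transcripts, and 138 and 2 and 9 and 0 for the share per gene.

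For the interaction and the average, 100 splits within the ages were drawn, the real one included. In the interaction 1 of 100, the real one, gave as many genes (4054, highest other 3342) and as many transcripts (2743, highest other 398). The real grouping of these libraries thus gave the most calls of the splits drawn. Chance differences between animals are not excluded by it, since the labels do not say that each library came from a separate animal. For the lists 23 of 100 splits gave as many (5, highest other 11), so chance is not excluded there in any sense. The split with 3342 genes exchanged replicate 3 of WT and of 5xFAD at 6 months and kept the other labels, so it shares most of its grouping with the real one. In the average 4 of 100 splits gave as many genes (104, highest other 1864), the real one included. The others, with 1864, 188 and 124 genes, kept the labels at 1 month and changed those at 6 months only. Such a split keeps the genotype difference at 1 month, so this count does not decide whether chance can be excluded for the average. The split with 1864 points to a structure of the samples. It kept the labels at 1 month and exchanged WT replicates 1 and 2 with 5xFAD replicates 2 and 3 at 6 months, so its average takes in the turn-over of the genotype difference, and a structure beside genotype was not tested.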

How the results depend on the processing

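The removal of the length and GC trend, of the 3 libraries richest in ribosomal RNA and of pseudogenes, mitochondrial and ribosomal RNA genes were chosen after the data were seen. Of 8989 recomputations of 520 results of named genes, 8117 had the direction and side of the threshold first found, 847 (of 227 genes' results) no longer passed, 10 passed newly and 15 changed sign. For named transcripts 897 were the same and 542 no longer passed, and for shares 246 and 87, with none reversed. No list called in a comparison changed direction under the alternatives run. Counts that moved by over 1.5 times follow, and the cause was not tested, beyond what fewer samples or a stricter criterion bring. With a 2-fold minimum, genes called numbered 481 at 1 month, 167 at 6 months, 282 with age in WT, 709 with age in 5xFAD, 1532 in the interaction and 26 averaged over both ages. Under it, transcripts called numbered 638 at 1 month, 275 with age in WT and 794 with age in 5xFAD. Adjusted over the retained-intron transcripts alone, retained-intron transcripts called numbered 86 at 1 month and 0 at 6 months. By the DESeq2 Wald test, genes called numbered 315 averaged over both ages. Under it, transcripts called numbered 5989 at 1 month, 3737 at 6 months, 4133 with age in WT, 6574 with age in 5xFAD and 8623 in the interaction. Under it, retained-intron transcripts called numbered 1040 at 1 month and 582 at 6 months. With no filter, genes called numbered 305 averaged over both ages. With the replicate block, genes called numbered 62 averaged over both ages. Under it, transcripts called numbered 368 at 1 month, 40 at 6 months, 110 with age in WT, 561 with age in 5xFAD and 1491 in the interaction. Under it, retained-intron transcripts called numbered 46 at 1 month and 1 at 6 months. With only the 6 samples compared, genes called numbered 501 at 6 months. Under it, transcripts called numbered 64 at 6 months, 222 with age in WT and 914 with age in 5xFAD. Under it, retained-intron transcripts called numbered 2 at 6 months. With the length and GC trend removed, genes called numbered 2015 at 1 month and 195 averaged over both ages. Under it, transcripts called numbered 2316 at 6 months, 1257 with age in WT and 5650 in the interaction. Under it, retained-intron transcripts called numbered 150 at 6 months. Without the 3 libraries richest in ribosomal RNA, genes called numbered 321 at 6 months, 1947 with age in 5xFAD, 2354 in the interaction and 167 averaged over both ages. Under it, transcripts called numbered 613 at 1 month, 122 at 6 months, 203 with age in 5xFAD and 961 in the interaction. Under it, retained-intron transcripts called numbered 50 at 1 month and 3 at 6 months. Under it, genes in the retained-intron share called numbered 26 at 1 month and 0 at 6 months. With a minimum of 50 counts, genes in the retained-intron share called numbered 300 at 1 month and 89 at 6 months. With the replicate block in limma on the logit share, genes in the retained-intron share called numbered 4 at 1 month and 0 at 6 months. With an estimated correlation in camera, lists called numbered 0 at 1 month, 0 at 6 months, 0 with age in WT, 0 with age in 5xFAD and 0 in the interaction. At an unadjusted p below 0.05 the preset correlation gave 11, 9, 9, 8 and 7 lists in that order. With fry, lists called numbered 15 at 1 month, 3 at 6 months, 17 with age in 5xFAD and 9 in the interaction. For Thy1 at 1 month, a difference that did not pass, the log2 value went from -0.00333 to 0.0133 with DESeq2 size factors, 0.0134 with the DESeq2 Wald test, 0.00985 with no filter, 0.015 with the 1 CPM filter, 0.0129 with only 6 samples, 0.25 with the length and GC trend removed, 0.0415 with the 3 libraries out and 0.0149 with pseudogenes, mitochondrial and rRNA genes out, and ran from -0.036 to 0.0494 with single replicates out. With the length and GC trend removed Thy1 with age in 5xFAD went from 0.0699 to -0.097, Thy1 in the interaction from 0.17 to -0.0921 and Hspa4l in the interaction from -0.76 to 0.12. The overall retained-intron share difference at 1 month (0.0364) was -0.203 without the 10 genes with the most such counts, -0.0974 without mitochondrially encoded genes and -0.0160 without the 3 libraries. The cause was not tested for these either. With each replicate of the compared groups left out in turn, genes called ran from 1893 to 2868 at 1 month, 276 to 1687 at 6 months, 780 to 1855 with age in WT, 2550 to 4014 with age in 5xFAD, 2905 to 4556 in the interaction and 43 to 130 averaged over both ages. Transcripts ran from 250 to 823 at 1 month, 36 to 486 at 6 months, 71 to 579 with age in WT, 432 to 1460 with age in 5xFAD and 1102 to 2832 in the interaction. Retained-intron transcripts ran from 30 to 102 at 1 month and 0 to 54 at 6 months, genes in the retained-intron share from 3 to 126 at 1 month and 0 to 58 at 6 months, and lists from 5 to 10 at 1 month, 4 to 6 at 6 months, 5 to 8 with age in WT, 5 to 9 with age in 5xFAD and 4 to 7 in the interaction. Lists with age in WT numbered 8 without WT at 6 months replicate 1. The overall share difference ran from -0.0304 to 0.156 at 1 month and -0.567 to -0.0880 at 6 months. Over the alternatives with the preset correlation, adjusted p of lists that lost their call reached 0.105 for visual cycle, 0.0959 for endothelium and 0.0671 for synapse at 1 month, 0.0665 for rod, 0.258 for pigment epithelium and 0.247 for heat shock at 6 months, 0.478 for ribosomal protein in WT, 0.0825 for blood in 5xFAD and 0.114 for endothelium and 0.0502 for heat shock in the interaction. With fry it was 0.0555 for ribosomal protein, 0.0564 for oxidative phosphorylation, 0.0538 for rod and 0.132 for pigment epithelium at 6 months, and 0.0606 for oxidative phosphorylation and 0.265 for ribosomal protein with age in WT. For genes it reached 0.204 for App at 1 month and 0.256 for Hspa5 at 6 months. The replicate numbers do not pair the libraries: 0 of 18 same-numbered pairs had r above 0.1 (-0.0852 to 0.0623, against -0.0814 to 0.0786 for others). In the simulated data, of the transcripts changed 4-fold at 1 month 5 of 66 were called, and at a mean of at least 10 CPM 31 of 66, against 52 of 66 genes, so low counts went with missed calls. Depth was not varied.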

Other observations

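The comparison of the ages averaged over both genotypes was chosen after the results were seen. It called 901 genes, 490 higher and 411 lower at 6 months. The count was 535 without WT at 1 month replicate 3, 480 without 5xFAD at 1 month replicate 2, and 580 without WT at 6 months replicate 3. Among genes that differ between mouse strains, the endosomal gene Wdfy1 was at 0.70 ± 0.20, adjusted p 0.0173 at 1 month, -0.68 ± 0.20, adjusted p 0.0485 at 6 months and -1.39 ± 0.29, adjusted p 0.00128 in the interaction. Single libraries ended its call at 1 month in 3 cases, and at 6 months in 5: adjusted p was 0.0744 without WT at 1 month replicate 1, 0.0950 without WT at 1 month replicate 2 and 0.0739 without 5xFAD at 1 month replicate 1 at the younger age and 0.199 without WT at 6 months replicate 1, 0.217 without WT at 6 months replicate 2, 0.146 without 5xFAD at 6 months replicate 1, 0.102 without 5xFAD at 6 months replicate 2 and 0.109 without 5xFAD at 6 months replicate 3 at the older. The lysosomal gene Entpd4 was at 0.53 ± 0.12, adjusted p 0.00338 at 1 month, and did not pass at 6 months (-0.17 ± 0.12, adjusted p 0.473). Its reads are uncertain, since 26.1% of its exon bases lie in a gene on the opposite strand and the preparation was unstranded. The photoreceptor polarity gene Crb1 did not pass at 1 month (-0.16 ± 0.16, adjusted p 0.517) and was at 0.77 ± 0.16, adjusted p 0.00992 at 6 months, with adjusted p 0.0768 without WT at 6 months replicate 1, 0.0656 without WT at 6 months replicate 2 and 0.169 without the 3 libraries richest in ribosomal RNA. The rod phosphodiesterase gene Pde6b did not pass at 1 month (0.01 ± 0.08, adjusted p 0.942) or 6 months (0.12 ± 0.08, adjusted p 0.40). Nnt, annotated as 2 genes, did not pass at 1 month (-1.57 ± 1.12, adjusted p 0.386 and 1.82 ± 1.28, adjusted p 0.376) or 6 months (-0.64 ± 1.11, adjusted p 0.815 and 0.43 ± 1.14, adjusted p 0.888). Since 100% of the exon bases of 1 of these lie in the other on the same strand, the split of reads between them is uncertain.

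In the edgeR fit, cholesterol synthesis genes were 4 higher and 1 lower of 20 (6 and 1 adjusted over the list alone; camera adjusted p 0.153) at 1 month, and 0 higher and 7 lower of 20 (0 and 7 adjusted over the list alone; camera adjusted p 0.165) with age in 5xFAD. Circadian clock genes were 3 higher and 4 lower of 20 (3 and 4 adjusted over the list alone; camera adjusted p 0.571) at 1 month and 2 higher and 3 lower of 20 (2 and 4 adjusted over the list alone; camera adjusted p 0.980) at 6 months. Oligodendrocyte and optic nerve genes were 1 higher and 0 lower of 7 (1 and 0 adjusted over the list alone; camera adjusted p 0.824) at 1 month. For cell cycle genes with age in 5xFAD there were 2 higher and 0 lower of 13 (2 and 0 adjusted over the list alone; camera adjusted p 0.490). Immediate early genes were 1 higher and 0 lower of 22 (0 and 0 adjusted over the list alone; camera adjusted p 0.864) at 1 month, ciliary body and iris genes 0 higher and 2 lower of 9 (1 and 2 adjusted over the list alone; camera adjusted p 0.646), and skeletal muscle genes 0 higher and 1 lower of 10 (0 and 0 adjusted over the list alone; camera adjusted p 0.223).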
